A study of Homo sapiens with 4 samples.

How the data were processed

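Chromatin immunoprecipitation sequencing was carried out on U251 cells, an established human glioblastoma line, that overexpressed the transcription factor SOX4 carrying an HA epitope tag. The 4 samples were 3 immunoprecipitations with an antibody to the HA tag (IP 1, IP 2 and IP 3) and 1 input of sheared chromatin, all taken 3 days after virus infection. Per the labels' protocols, the replicate libraries came from independent immunoprecipitations. Nothing in the labels says that they came from separate cultures or infections, so the tests below measure only the spread between these immunoprecipitations.

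Per the labels' protocols, the libraries were sequenced as single-end reads. Per the submitters' processing notes, the tools were bcl2fastq 2.20, Bowtie2 2.3.3.1, Picard 2.10, MACS2 2.1.1.20160309 and HOMER 4.9.1, and the genome build was hg19. Per the file headers, the authors called peaks separately in each immunoprecipitation against the same input, on alignments named as filtered and stripped of duplicates. The headers give no peak model, an extension of 163, 155 and 179 bp for IP 1, IP 2 and IP 3, an effective genome size of 2.7e+09 bp and a q threshold of 0.05. The larger library was scaled down to the smaller one, and the local background was taken over windows of 1 kb and 10 kb. How reads with several equally good positions were treated is not given in the sources used here. This matters for genes with near-identical copies, whose peaks can be lost or misplaced.

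Each deposited list gives, per peak, its start, end, width and summit on hg19, counted from 1. The pileup is a signal, the height of extended reads at the summit, as deposited by the authors on the scale of the immunoprecipitation. The fold enrichment is the authors' ratio of pileup to local background, each with 1 added. The −log10 p and −log10 q values are those deposited by the authors for the Poisson test at the summit. From each peak's pileup and fold enrichment the local background was recovered. A Poisson tail computed from it matched the deposited −log10 p to within 0.000212 in every peak of the 3 lists. A score or fold belongs to the authors' peak call and is used here to describe and rank peaks within a list, or to describe the spread over the 3 immunoprecipitations.

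Peaks of the 3 lists that overlapped by at least 1 bp were merged into regions, and a region with a peak of every immunoprecipitation is called shared. Where a region held several peaks of an immunoprecipitation, the highest fold was taken. The number of shared regions was compared with 1000 random placements of every peak within its chromosome, between its first base and the last peak end of any list, so the smallest p that the placements can give is 0.001. Fold enrichment was compared across shared regions by Spearman's rho. Because the 3 calls share the input, a rho from the shared background was simulated by shuffling pileups over regions within each immunoprecipitation. The shuffling breaks the tie between pileup and background that peak calling imposes. The background that uniform input gives was simulated as the highest of the genome average and the Poisson counts in windows of the fragment length, 1 kb and 10 kb. Shared regions no more than 50 kb apart were joined into clusters. Permutation tests used 100000 resamples and are two-sided, placement tests are one-sided, and intervals on shares are exact 95% Clopper-Pearson intervals that cover counting error only. PCR reads without molecular identifiers are not independent molecules.

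An hg19 genome sequence and gene annotation were not used here, so no peak was assigned to a gene, an exon or a promoter. The only gene table was that of RefSeq on assembly GRCh38.p14. It served for gene symbols, gene types, the chromosome that carries each gene and the order of neighbouring genes, and none of its positions was compared with a peak. For this reason the planned tests of gene starts, tRNA genes by position, tRNA isotypes, other RNA polymerase III genes, the SOX motif, the B box motif, gene lists and enrichment at tRNA regions were not run, nor were their alternatives. The comparison of region numbers with gene numbers per chromosome and the clustering of regions were added after the data had been seen. Runs of tRNA genes are tRNA genes with no other gene of the table between them. The 22 mitochondrial tRNA genes were left out.

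The regions described individually follow a rule fixed before the data were examined, namely the 20 shared regions with the highest mean fold enrichment. The parts of that rule that name genes, among them the SOX4 locus, could not be applied. Clusters of 5 or more regions and the chromosome 6 window were chosen after their values were seen. On simulated lists of the same sizes and peak widths with 200 planted sites, the procedure found 200 in each of 10 runs, and at most 0 with no planted site. Each planted site was put into all 3 lists at nearly the same position, so it could hardly be missed. These runs check only the counting, not how many real sites a list misses. Alternatives were regions of at least 2 lists, a reciprocal overlap of 50%, a q of 1e-10 or less, each immunoprecipitation left out, and other placements. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.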

Results

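The series maps where HA-tagged SOX4, a transcription factor of the HMG-box family, sat on chromatin in U251 glioblastoma cells, and its title names the repression of specific tRNA genes as the question. After removal of duplicates, the peak calls rested on 24037735 tags in IP 1, 23683012 in IP 2 and 19228143 in IP 3. The 1 input held 28755427 tags and served as the background of all 3 calls. The input has no peak list of its own, so each comparison of immunoprecipitated with input chromatin is the one made within the authors' peak call.

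IP 1 gave 627 peaks, IP 2 gave 524 and IP 3 gave 407. The peaks were narrow, with median widths of 221, 208 and 237 bp, and together covered 148.8 kb, 115.9 kb and 104.5 kb. Median fold enrichment over the local input background was 6.36 in IP 1, 6.52 in IP 2 and 6.91 in IP 3. The highest folds were 28.0, 27.4 and 27.0. The median pileup at the summit was 22, 23 and 22 reads. IP 3, with the fewest tags, had the fewest peaks. IP 1 and IP 2 differed in tags by a factor of 1.015 and in peaks by a factor of 1.197.

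The 3 lists merged into 862 regions, of which 263 held a peak of every immunoprecipitation, 159 a peak of exactly 2 of them and 440 a peak of only 1. No shared region arose in any of 1000 random placements of the peaks (highest count 0, one-sided permutation p = 0.001, the smallest the placements can give). Peaks this narrow hardly ever meet when spread over chromosomes, so this p does not separate binding from an artefact common to the 3 calls. When each peak was moved by at most 10 kb from its own position, the placements gave 1.46 shared regions on average and 7 at most. The shared regions held 42.3% of the peaks of IP 1 (95% interval 38.4% to 46.2%), 51.3% of IP 2 (47.0% to 55.7%) and 65.1% of IP 3 (60.3% to 69.7%). Summits of the 3 immunoprecipitations lay within 50 bp of one another in 165 of the 263 regions, and their median range was 37 bp.

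Peaks in shared regions had higher fold enrichment than the other peaks of the same list. The medians were 8.62 against 5.54 in IP 1, 8.55 against 5.59 in IP 2 and 7.65 against 5.71 in IP 3. Each difference gave a permutation p of 1e-05, the smallest that 100000 resamples can give. A peak near the calling threshold in 1 list is more easily missed in the others, so a difference in this direction is partly built in. The permutation also treats neighbouring peaks as independent. In the highest quartile of each list by fold, 139 of 157 peaks of IP 1, 124 of 131 of IP 2 and 98 of 102 of IP 3 lay in shared regions. In the lowest quartile the numbers were 19 of 156, 29 of 131 and 38 of 101.

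**Figure D1:**
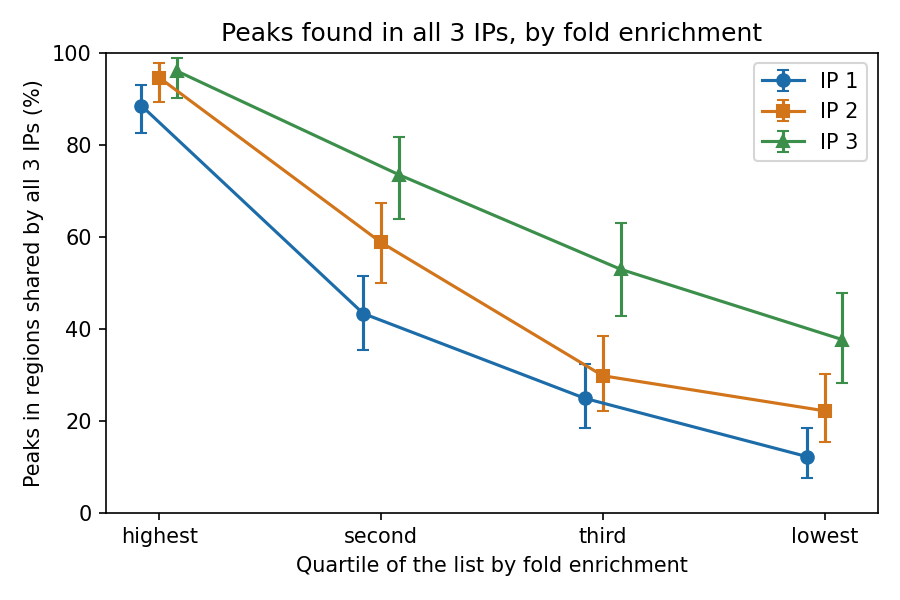
Percentage of peaks that lie in regions shared by all 3 immunoprecipitations (vertical axis) in each quartile of a list ordered by fold enrichment (horizontal axis), with 1 line per immunoprecipitation and exact 95% intervals as bars. The share falls from 88.5% to 12.2% in IP 1, from 94.7% to 22.1% in IP 2 and from 96.1% to 37.6% in IP 3.

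The strongest shared regions lay on 7 chromosomes, and 6 of the top 20 were on chromosome 17. The highest was on chromosome 7 from 5465100 to 5465463 (hg19), at 26.7 ± 0.93-fold over input (SD, n = 3). A region on chromosome 7 from 90893554 to 90893875 reached 24.0 ± 0.48-fold. Chromosome 17 held a region from 79367674 to 79368003 at 23.4 ± 2.84-fold and another from 42634501 to 42634824 at 21.8 ± 6.07-fold. The second of these spread most, from 15.8-fold in IP 2 to 28.0-fold in IP 1. On chromosome 1, the region from 93544565 to 93544895 reached 20.3 ± 1.74-fold and that from 17293846 to 17294158 reached 16.6 ± 3.27-fold.

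Below these, regions on chromosomes 5, 6, 15, 17 and 19 had mean folds between 13.6 and 15.9. On chromosome 6, the regions from 26568956 to 26569248, from 27144857 to 27145202 and from 28949322 to 28949665 reached 15.9 ± 3.05-fold, 15.2 ± 3.36-fold and 15.2 ± 3.17-fold. On chromosome 17, a region from 37025390 to 37025813 reached 15.7 ± 1.62-fold and one from 71338311 to 71338668 reached 14.4 ± 2.22-fold. A pair of adjacent regions there, from 8089514 to 8089829 and from 8090026 to 8090676, reached 14.3 ± 0.57-fold and 15.3 ± 2.06-fold. Chromosome 5 held regions from 180633702 to 180634122 at 15.6 ± 4.07-fold, from 81047099 to 81047475 at 14.7 ± 2.04-fold and from 81147628 to 81147945 at 14.5 ± 1.73-fold. The remaining regions of the top 20 were 3 on chromosome 19 and 1 on chromosome 15, with means of 13.6 to 14.3. Each of the 20 had a −log10 q of at least 14.3 in every list. Neighbours in this order often differed by less than their SDs, so the order itself is not firm.

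**Figure D2:**
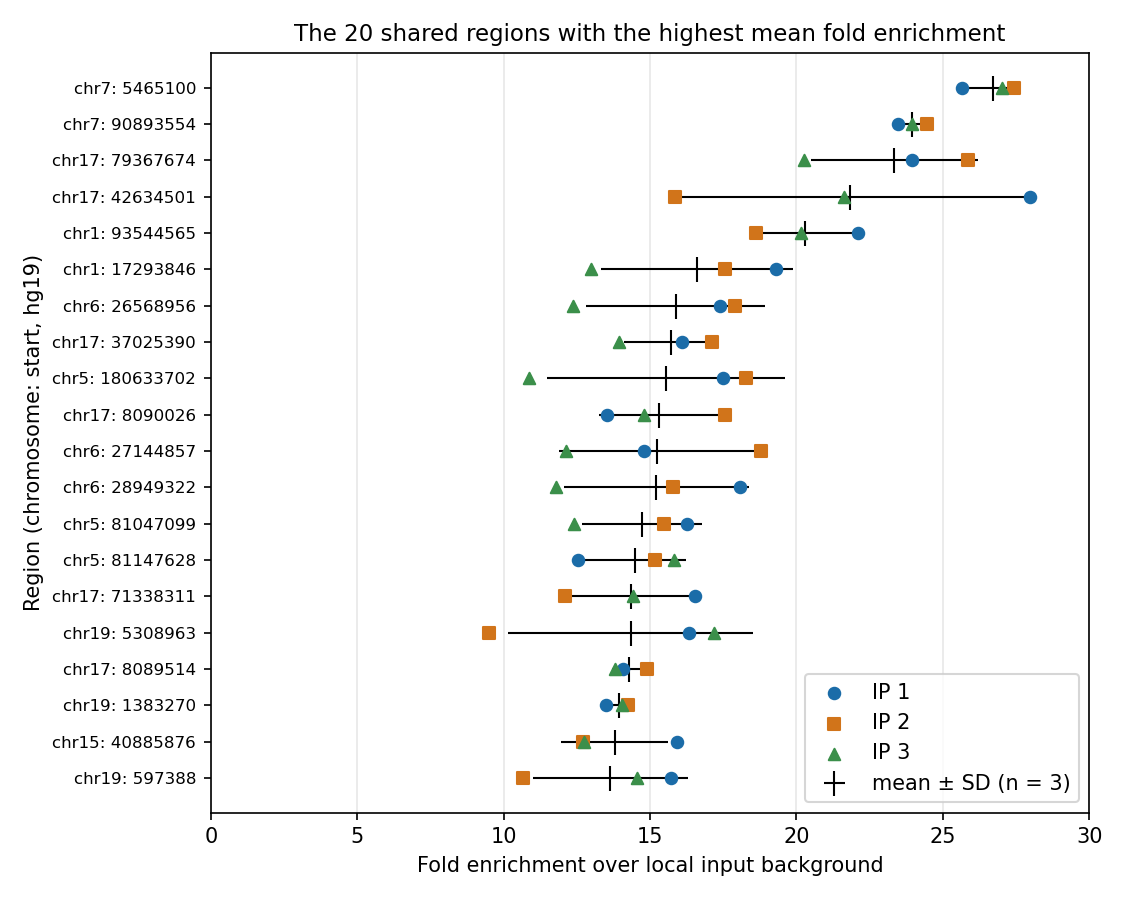
Fold enrichment over the local input background (horizontal axis) of the 20 shared regions with the highest mean (vertical axis, chromosome and start on hg19), with 1 symbol per immunoprecipitation and the mean ± SD of the 3 in black. Means run from 13.6 to 26.7, and the region on chromosome 17 that starts at 42634501 has the widest spread.

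Over all 263 shared regions, mean fold enrichment ran from 2.78 to 26.7 with a median of 8.23, and the median coefficient of variation over the 3 immunoprecipitations was 15.5%. Across regions, Spearman's rho of the folds was 0.71 between IP 1 and IP 2, 0.71 between IP 1 and IP 3 and 0.68 between IP 2 and IP 3. These are correlations across regions, which are not independent replicates. The 3 folds share the input in their denominators, and with pileups shuffled over regions the mean rho was 0.35, 0.36 and 0.34. The shuffling can pair a low pileup with a high background, which peak calling would reject. The simulated values therefore need not equal what the shared input gives among called regions. The covariance of log2 folds was 0.215, 0.205 and 0.185 against 0.169, 0.170 and 0.161 simulated. The pileup, into whose value the input does not enter, gave a rho of 0.75, 0.74 and 0.72. The regions were still chosen by calls against the same input, so this rho is not free of it. The backgrounds of the same pairs had a rho of 0.89, 0.89 and 0.87 across regions.

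Shared regions gathered in clusters, most often on chromosome 6, where 6 of the 8 clusters of 5 or more regions lay. Of the 263 shared regions, 125 (47.5%) had another within 50 kb, against 4.64 on average and 18 at most in random placements within chromosomes (one-sided permutation p = 0.001, the smallest possible). When each region was moved by at most 1 Mb, the placements gave 54.4 on average and 74 at most. Of the regions found in 1 list alone, 54 of 440 (12.3%) had another of their kind within 50 kb, against 8.38 in random placements.

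The 8 clusters of 5 or more shared regions held 68 regions. On chromosome 6 lay 6 of them, with 7 regions from 26286656 to 26330721, 7 from 26521388 to 26572276, 5 from 27446507 to 27487450, 8 from 27551167 to 27656191, 5 from 28557080 to 28626225 and 14 from 28687364 to 28950155. The short arm of chromosome 6 is known to carry the largest assembly of tRNA genes, beside the main histone gene cluster. The other two were 13 regions on chromosome 17 from 8022397 to 8130516 and 9 on chromosome 5 from 180600550 to 180649605. Median mean folds within these 8 clusters ran from 8.03 to 10.7. No such cluster lay on another chromosome. The largest elsewhere had 4 regions, on chromosome 11 from 59318041 to 59334041, with a median mean fold of 11.3.

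Chromosome 6 held 59 of the 263 shared regions (22.4%) and 24 of the 440 regions of a single list (5.45%), an odds ratio of 5.01 (Fisher's exact test, two-sided, p = 3.7e-11). Of the 59, 53 lay in a window of 2.66 Mb from 26286656 to 28950155, which also held 13 of the single-list regions. The window was drawn from the shared regions themselves. Neighbouring regions are not independent, so the p-value is smaller than separate sites would give, and chromosome 6 held 9.41% of the shared sites when each cluster was counted once. That is much nearer the 5.45% of single-list regions, so most of the contrast rests on clustering. Single-list regions were not collapsed in this way, and no test was made with clusters counted once.

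**Figure D3:**
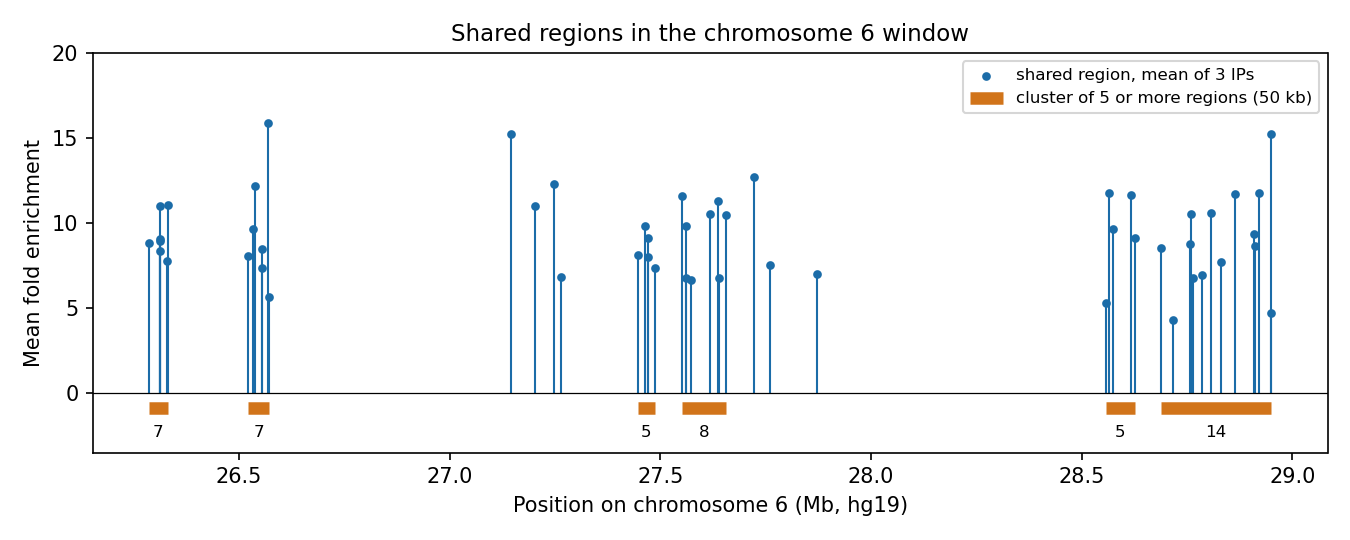
Mean fold enrichment of the 3 immunoprecipitations (vertical axis) of the 53 shared regions in the chromosome 6 window, by position on hg19 in Mb (horizontal axis). Orange bars mark the 6 clusters of 5 or more regions, with the number of regions under each, and the tallest region reaches 15.9-fold.

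To relate the regions to tRNA genes without placing a peak at a gene, the number of regions on each of 23 chromosomes was set against the number of genes of 8 types in the GRCh38 table. Chromosomes with more nuclear tRNA genes held more shared regions. The table has 443 such genes, 155 of them on chromosome 6 (59 shared regions), 98 on chromosome 1 (33 regions), 33 on chromosome 17 (29 regions), 26 on chromosome 16 (13 regions), 22 on chromosome 7 (11 regions), 19 on chromosome 14 (10 regions) and 18 on chromosome 5 (17 regions). Chromosome 3, with 4 tRNA genes and 1066 protein-coding genes, held 3 shared regions, and chromosome X, with 4 tRNA genes and 848 protein-coding genes, held 1. The relation was not strict, since chromosomes 15, 19 and 12, with 9, 7 and 9 tRNA genes, held 16, 15 and 14 shared regions.

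Pearson's r with tRNA genes was 0.93 and Spearman's rho 0.87, each with a permutation p of 1e-05, the smallest possible (adjusted p of rho over 8 gene types 8e-05). Without chromosomes 1 and 6, the farthest from the median number of tRNA genes, r was 0.82. Protein-coding genes gave a rho of 0.68 (permutation p = 0.0005, adjusted 0.002), and the other types gave rho between 0.39 and 0.60. With the number of protein-coding genes held fixed, the partial rank correlation with tRNA genes was 0.77 (permutation p = 3e-05, adjusted over 7 types 0.00021). No other type passed 0.05. Replication-dependent histone genes gave 0.37 (permutation p = 0.0795, adjusted 0.192), but 55 of the 69 are on chromosome 6, 13 on chromosome 1 and 1 on chromosome 12, so counts over chromosomes can hardly test them.

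Regions of a single list followed tRNA genes less closely. Their rho was 0.49 (permutation p = 0.0189), and with protein-coding genes held fixed it was 0.10 (permutation p = 0.666). The difference of 0.67 between shared and single-list regions in the partial rank correlation compares with 0.28 on average over 10000 shuffles of the 2 kinds among clusters of equal size (two-sided permutation p = 0.0096). The chromosome is a coarse unit, and these correlations do not say which regions lie at tRNA genes.

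**Figure D4:**
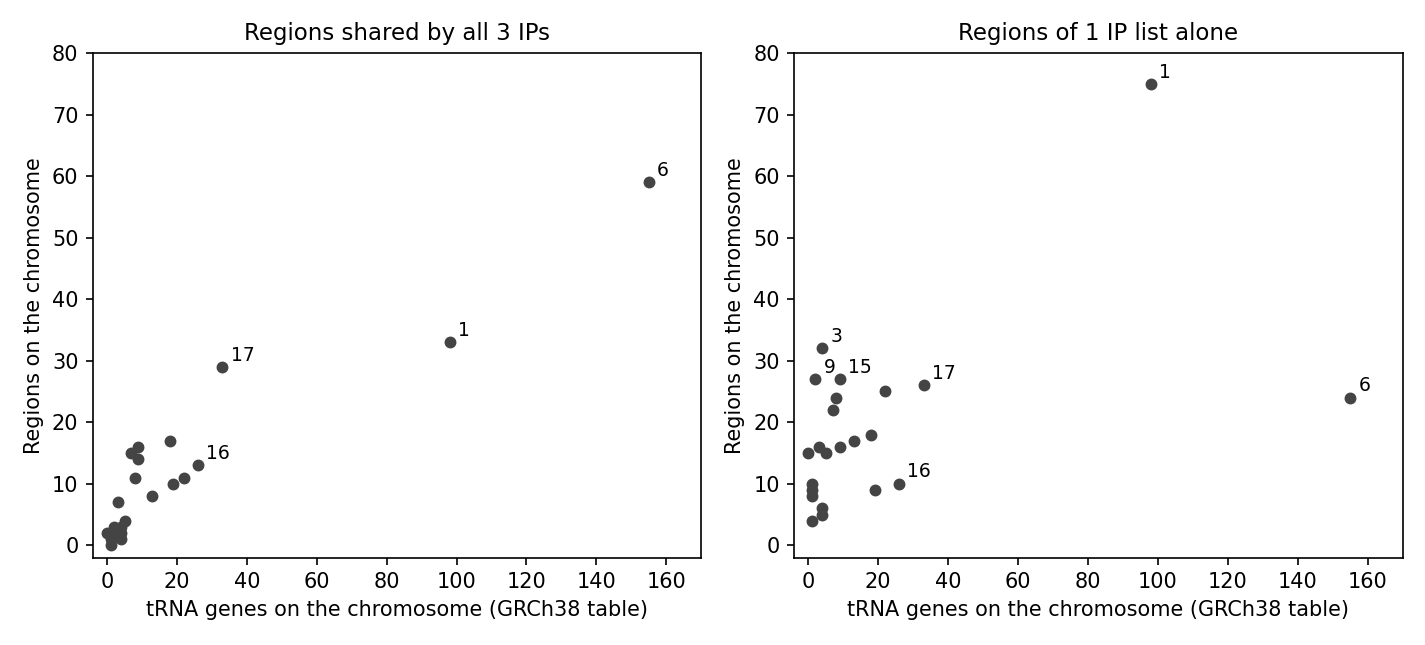
Number of regions shared by all 3 immunoprecipitations (left, vertical axis) and of regions of 1 list alone (right, vertical axis) against the number of nuclear tRNA genes on the chromosome in the GRCh38 table (horizontal axis), with 1 point per chromosome and names where points stand apart. Chromosome 6, with 155 tRNA genes, has 59 shared and 24 single-list regions, and Spearman's rho is 0.87 on the left and 0.49 on the right.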

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

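The choice of regions moved counts more than directions. Regions of at least 2 lists numbered 422 and those at a q of 1e-10 or less 151, against 263 shared regions, and leaving out 1 immunoprecipitation in turn gave 290 to 359 regions common to the others. A reciprocal overlap of 50% gave 252, a fold of 4 or more 254, and leaving out chromosome 6 gave 204. In every one of these except the reciprocal overlap, which was not placed at random, no placement reached the observed count (permutation p = 0.001). Narrow peaks placed at random hardly ever meet, so this p would follow for any lists with a common source, artefact included. The number of clustered regions, 125, became 80 at the stricter q, for which fewer regions enter, and 74 without chromosome 6, and ran from 130 to 162 with 1 immunoprecipitation left out. The share of shared regions on chromosome 6, 22.4%, became 9.41% when each cluster was counted once, as its construction implies, and lay between 20.5% and 21.4% with 1 immunoprecipitation left out. The rho with tRNA genes over chromosomes, 0.87, was 0.83 without chromosomes 6 and 1 and 0.83 with clusters counted once. It lay between 0.84 and 0.88 for the other definitions of shared regions and was 0.49 for peaks of 1 list alone. The rho of folds between immunoprecipitations kept its sign under its 3 alternatives, the lowest being 0.60 for IP 1 and IP 3 at the stricter q. The alternatives planned for tests that need hg19 gene positions or sequence were not run. No paired analysis was possible because the only group with several samples is the immunoprecipitation, and the input is 1 sample with no list of its own. Depth limits the weak end of each list, where peaks rest on 10 to 12 reads at the lowest, so a region missing from a list is not shown to be unbound in that immunoprecipitation.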

Other observations

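The longest 2 runs of neighbouring tRNA genes lay on chromosomes without a large cluster of shared regions. In the gene order of the GRCh38 table, 17 runs hold 5 or more tRNA genes, 11 on chromosome 6, 2 on chromosome 5 and 1 each on chromosomes 1, 7, 11 and 16. Loci with tRNA-like names that the table does not type as tRNA genes also end a run, so these counts depend on that rule. On chromosome 16, TRP-TGG4-1 parts runs of 4 and 6 tRNA genes, and on chromosome 14, TRL-TAG4-1 parts runs of 3 and 3. The longest, 26 genes from TRE-TTC4-2 to TRG-GCC4-1, is on chromosome 1, where the largest cluster held 3 shared regions. The next, 12 genes from TRC-GCA22-1 to TRC-GCA9-4, is on chromosome 7, where the largest cluster held 2. Runs follow gene order and clusters follow distance, so they are not like units. No region or cluster was placed at a run, so the clusters named need not lie near these runs. Chromosomes 1 and 7 held 33 and 11 shared regions, any of which may lie nearer. Peaks at near-identical copies can also be lost. These 2 runs are therefore not shown to be free of SOX4. Chromosome 17, which held a cluster of 13 regions, has several short runs, among them 3 tRNA genes between ALOXE3 and HES7, 4 between HES7 and PER1, 4 between LINC00324 and CTC1 and 3 between CTC1 and PFAS. There were 33.7 shared regions per 100 tRNA genes on chromosome 1, 38.1 on chromosome 6, 87.9 on chromosome 17 and 94.4 on chromosome 5. Chromosomes 7, 16 and 11, with runs but no clusters of 5 or more, had 50, 50 and 61.5, above chromosome 6. These ratios count regions that may lie away from tRNA genes, and the rho of 0.87 across chromosomes became 0.83 without chromosomes 6 and 1. Chromosomes 15 and 19, with 9 and 7 tRNA genes, held 16 and 15 shared regions.

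Some peaks rose from a high input background. IP 3 alone had a peak on chromosome 1 from 121484605 to 121485315 with a pileup of 258 reads and a fold of 1.49, and one on chromosome 7 from 61969075 to 61969259 with 182 reads and a fold of 1.45. Their backgrounds were 136 and 98.1 times the genome average. On chromosome 11, peaks of all 3 immunoprecipitations between 62608829 and 62609239 stood on backgrounds of 11.5 to 13.2 times the average, with folds of 2.32 to 3.42. At the median peak the background was 1.73, 1.82 and 1.88 times the genome average in IP 1, IP 2 and IP 3. Uniform input reads passed through the same maximum over windows gave 1.15, 1.21 and 1.13 in simulation. In step with whole input reads (tolerance at least 0.0002 reads), the background was set by the window of 1 fragment length at 41.3%, 42.7% and 46.2% of peaks, by 1 kb at 38.0%, 41.0% and 34.2%, by 10 kb at 16.4%, 13.2% and 15.7%, and by the genome average at the rest.

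The tests in the following paragraphs on low input, depth, tRNA genes and histone genes were chosen after values they use had been seen, and those on neighbourhoods and copies before their own results, though after the patterns they address. The 3 lists shared 263 regions. If input below the genome average had made them, their peaks would have the genome average, the lowest background the caller allows, at least as often as under uniform input, which gave 18.0% to 19.8% in simulation. At most 3.72% did in any immunoprecipitation (exact 95% interval 1.80% to 6.73%). Yet where a wider window set the background, input at the peak itself could still lie below the genome average. This share therefore cannot decide the question. The lowest pileup at peaks of shared regions was 7.58, 9.56 and 9.41 times the genome average in IP 1, IP 2 and IP 3. Because the background cannot fall below that average, these heights argue against input below it as the sole source of the peaks. Input that was low for its surroundings, yet above the genome average, was not tested. When each peak was moved by at most 10 kb, at most 7 shared regions arose. With median widths of 208 to 237 bp, few peaks could meet after such moves, whatever had brought them together. The count shows only that the overlap is finer than random placement within 10 kb. Confinement of the peaks to the same much narrower stretches was not tested. Which factor other than tagged SOX4 the antibody may have brought down stays open, since no immunoprecipitation without the tag is among the samples used here, and the design gives no other group against which a biological explanation of this overlap was tested.

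IP 1 had more peaks than IP 2 at nearly the same depth. Regions of IP 1 missing from IP 2 outnumbered the reverse by 1.66 times (267 against 161, exact 95% interval 1.36 to 2.03), with a ratio of tags of 1.015. The excess thus arose at nearly equal depth. A ratio of regions is not on the scale of a ratio of tags, so their comparison cannot decide what part depth had. The calls also differed in extension, 163 bp for IP 1 and 155 bp for IP 2, which was not weighed. Against IP 3 the factor was 3.13 (322 against 103, interval 2.497 to 3.94) with a ratio of tags of 1.25. There, depth and the yield of the immunoprecipitation cannot be told apart, because the number of peaks need not follow tags in proportion and the deeper library is also the one with more peaks.

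The gathering on chromosome 6 could come from extra copies of that stretch in these cells, which would raise the input there. The median background over the genome average was 1.67 in the window and 1.99 at the other shared regions, a ratio of 0.842 (bootstrap 95% interval 0.712 to 0.975). The input at these peaks thus gave no sign of extra copies. At most peaks the background was set by a window of 1 fragment length or 1 kb, so it also follows local differences in input. Such differences could hide a gain, which is not excluded. Histone genes stay open, since only 1 chromosome other than 6 and 1 carries a replication-dependent histone gene, too few for a correlation over chromosomes. A hypothesis consistent with the counts is that many shared regions lie at tRNA genes. Over the chromosomes other than 6 and 1, the partial rank correlation with tRNA genes was 0.727 (permutation p = 0.00022, adjusted over 7 gene types 0.00154). Reads shared between near-identical tRNA genes, and a general pull-down of densely transcribed chromatin, stay open as untested.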
